A study of Homo sapiens with 6 samples.

How the data were processed

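Total RNA of 6 MDA-MB-231 samples, 3 with siPTHrP and 3 with siLuc, had been isolated with RNeasy columns, labelled with biotin and hybridised to Affymetrix human genome U133 arrays, type A, 1 array per RNA, per the labels' protocols. The deposited values were linear signal intensities computed with MAS5, per the submitters' processing notes, and its version and settings are not given in the sources used here. The mean of these intensities after trimming 2% at each end lay between 1500.4 and 1500.6 on all 6 arrays, as global scaling to one target gives, so the deposited scaling was kept. Values of the siLuc array of experiment 1 carried decimals in 90.1% of probe sets, while those of the other 5 arrays were whole numbers. MAS5 subtracts mismatch signal, so low intensities are noisy and fold changes of dim probe sets have large errors. Detection calls were not used here.

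Groups were taken from the titles and descriptions. The design text states that the number in a sample's name marks 1 of 3 independent experiments and that RNAs of the same experiment were compared, so the experiment number was a block in the main analysis, decided before the data were examined. The siLuc sample without a number was taken as experiment 1 by elimination. The sample titled as the siLuc RNA of experiment 3 carries number 2 in its description, and the title was followed. The pairing was checked by correlating deviations from the group means across probe sets: same-experiment pairs gave -0.012, 0.157 and 0.157 for experiments 1, 2 and 3, and the other 6 combinations gave -0.206 to 0.132. Without a replicate block in the model, 0 probe sets and 3 gene lists passed, as in the paired analysis.

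Analysis used R 4.3.3 and limma 3.58.1. Of 22283 probe sets 68 controls were left out, and probe sets were kept where the mean of log2(intensity + 16) over the 6 arrays was at or above its 40th percentile (8.614, a signal of about 376), which left 13329. The offset of 16 shrinks fold changes of dim probe sets. A linear model with siRNA and experiment was fitted with lmFit and eBayes with an intensity trend, with 2 residual degrees of freedom and a prior of 7.17. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05, and fold changes are siPTHrP over siLuc on the log2(intensity + 16) scale. The median log2 fold change of all kept probe sets was 0.030, and it was 0.094 with quantile normalization and 0.11 with median centring.

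Probe sets were named from the array's annotation table. One gene was listed for 19071 probe sets, several for 1043 and none for 2169, and probe sets with several or no gene were not named. Symbols of 19059 probe sets were updated through their Entrez identifiers to the RefSeq names of GRCh38.p14, and no coordinates were used. The transcript targeted by the siRNA was not analysed here, so the knockdown itself, which would check the labels, was not checked.

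The named genes followed a rule written before the data were examined: the 12 largest rises and 12 largest falls among probe sets past the threshold with the same direction in all 3 experiments, filled up, where fewer than 12 passed, by the smallest unadjusted p among probe sets with an absolute log2 fold change of at least 1 and the same direction in all 3, plus up to 4 members per gene list with the smallest p and the members that passed. Since 0 probe sets passed, all 24 came from the second part. Lists of 26 pathways and cell type markers were fixed beforehand. Of their symbols 640 were on the array by name and 72 were not. Each gene was represented by its brightest probe set, so that a gene can have another value in its list than among the 24, and 25 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01. With an estimated correlation 0 lists passed, and with fry, which asks whether a list's genes move one way on balance, 0 passed. The mixed form of fry, which asks for change in either direction, gave 3.

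The steps were tested on simulated data with each array's own noise. Of 100 probe sets changed by a log2 of 1 among 13329, 17% were recovered, and of 100 changed by 2, 64.8%, with 0.2 false calls per run over 5 runs. With the noise of the other 5 arrays on every array these shares were 44.4% and 88.4%, with 5.4 false calls. The simulated noise was normal and equal for probe sets of like intensity on an array, with no effect of the experiment. These shares may therefore be too high for the real arrays. Simulated lists of 40 independent probe sets shifted by 0.5 had an unadjusted camera p under 0.05 in 100% of 20 draws, and unshifted ones in 0%. This is an easier threshold than the adjusted p used for the real lists.

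Alternatives fixed beforehand were no replicate block, offsets of 1 and 64, quantile normalization, median centring, no filter or one at the 60th percentile, no trend, a robust trend, array weights, leaving out _x_at and _s_at probe sets, leaving out each experiment, an estimated correlation, the mean of all probe sets of a gene, fry, and a rule of at least 1.5-fold in each experiment with no test. The model without a block and without the siLuc array of experiment 1, the one without a block and with array weights, and the estimated correlation in fits with no filter or without 1 experiment were chosen after seeing the data.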

Results

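Expression was measured in MDA-MB-231, an established human breast cancer cell line with a mesenchymal-like phenotype that is widely used in models of bone metastasis. Cells were electroporated with an siRNA directed at parathyroid hormone-related protein (siPTHrP) or with a control siRNA directed at firefly luciferase (siLuc), and total RNA was collected after 3 days. PTHrP is a secreted peptide that acts through the receptor it shares with parathyroid hormone and is known for its part in bone destruction by breast cancer cells. The electroporation was carried out in 3 independent experiments, each giving 1 siLuc and 1 siPTHrP RNA, so that each group held 3 arrays. Each array gave a signal for 22283 probe sets, with a median signal between 559 and 887 and a trimmed mean between 1500.4 and 1500.6. The number of arrays limits the precision of every value.

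The siLuc array of experiment 1 stood apart from the other 5. Its Spearman rank correlation with them, across probe sets, lay between 0.716 and 0.725, whereas those 5 arrays correlated with each other at 0.882 to 0.960. Its spiked hybridisation controls, 18 probe sets for bacterial and phage transcripts added in a fixed amount, had a geometric mean signal of 273100. The siLuc arrays of experiments 2 and 3 gave 22870 and 41430, and the siPTHrP arrays of experiments 1, 2 and 3 gave 10840, 11660 and 40210. The 3'/5' signal ratio of GAPDH lay between 0.845 and 1.11 on the 6 arrays, with 1.05 on the siLuc array of experiment 1. That of ACTB was 1.5 on this array, the highest, and 0.842 to 1.36 on the other 5. Its 9 control probe sets for ribosomal RNA had a geometric mean of 134200, and the siLuc arrays of experiments 2 and 3 gave 22320 and 20850. The siPTHrP arrays of experiments 1, 2 and 3 gave 1155, 4021 and 22500. Between the groups these controls stood at 0.119-fold (siPTHrP over siLuc) and the hybridisation controls at 0.27-fold, but the groups overlapped in both. An exact two-sided permutation test of 3 against 3 arrays gave p = 0.3 and 0.2, where 0.1 is the smallest possible. In experiment 3 the 2 arrays were alike in both.

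**Figure D1:**
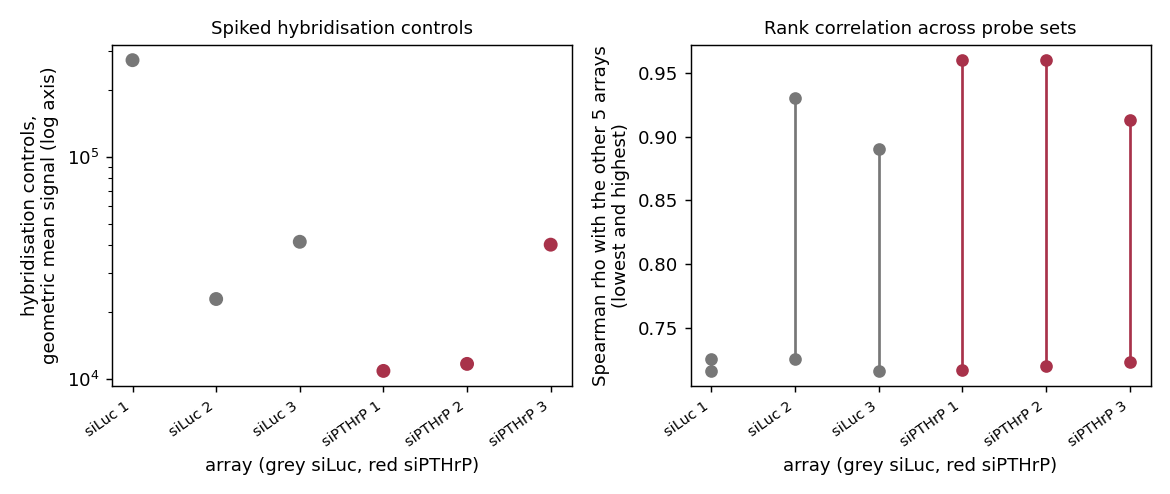
Quality measures of the 6 arrays (grey, siLuc; red, siPTHrP). The left panel gives the geometric mean signal of 18 hybridisation control probe sets per array on a log axis, and the right panel the lowest and highest Spearman correlation of each array with the other 5; the siLuc array of experiment 1 has the highest controls (273100) and correlates with no other array above 0.725.

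The comparison asked which transcripts respond to the siRNA against PTHrP, by setting siPTHrP against siLuc RNA of the same experiment. Genes of G2/M and mitosis rose as a group with siPTHrP, with a median of 1.48-fold over 38 genes and a shift in the same direction in each experiment. This rise passed limma's camera test with a preset correlation between genes (adjusted p = 5.31e-09) but not with an estimated one (adjusted p = 0.440 with an estimated correlation) or with fry (adjusted p = 0.0742). Single genes with the smallest p-values included JAG1, a Notch ligand, at 2.71-fold of the siLuc level, and KISS1, a metastasis suppressor, at 0.408-fold. No single probe set passed the threshold. With limma and the experiment as a block, 0 of 13329 probe sets had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.133. At an unadjusted p under 0.05 there were 1618 probe sets, 903 higher and 715 lower with siPTHrP, where 666 are expected by chance. Which direction held more of them depended on the setting: 984 were higher and 1529 lower with no filter, 460 and 865 with no intensity trend, and 1131 and 527 with median centring. The difference had the same sign in all 3 experiments for 5080 probe sets, or 38.1%, where chance gives 25%. The count of 0 did not hold when any 1 experiment was left out: 33 probe sets passed without experiment 1, 47 without experiment 2 and 215 without experiment 3. Such fits have fewer residual degrees of freedom than the 2 of the main fit. Their p-values lean more on the prior variance shared by probe sets of like intensity. With estimated array weights, which were 0.386, 2.232 and 1.161 for experiments 1, 2 and 3, 177 passed (100 higher, 77 lower).

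The genes with higher signal and the smallest p-values, none past the threshold over all probe sets, were led by JAG1 and TAGLN2. JAG1 had a signal of 2573 ± 316 with siLuc and 7031 ± 1170 with siPTHrP (SD, n = 3), a log2 fold change of 1.44 (SE 0.19, limma adjusted p = 0.133). TAGLN2, an actin-binding protein, went from 2939 ± 576 to 7883 ± 1060 (1.43, SE 0.19, adjusted p = 0.133). The histone variant H2AZ1 had 9575 ± 2430 and 21550 ± 3530 (1.19, SE 0.17, adjusted p = 0.135), and the adhesion molecule AMIGO2 had 7877 ± 1430 and 16290 ± 2360 (1.05, SE 0.17, adjusted p = 0.215). The mitotic kinase CDK1 showed 2.28-fold, TMPO, a protein of the nuclear lamina, 2.45-fold, and DPYSL2, which binds tubulin, 2.61-fold the siLuc signal. S100P, a calcium-binding protein, stood at 2.30-fold, CYCS (cytochrome c) at 2.16-fold, SAT1, an enzyme of polyamine breakdown, at 2.41-fold, and TNFRSF12A, the receptor of the cytokine TWEAK, at 2.38-fold. PAIP1, a partner of the poly(A)-binding protein, stood at 2.96-fold on one probe set, but only 2 of its other 4 probe sets had the same sign. Adjusted p-values of these last 8 genes lay between 0.219 and 0.290, and each gene was higher in 3 of 3 experiments, as the naming rule required. Other probe sets gave smaller differences for several of these genes: 1.27-fold for H2AZ1 and 1.31-fold for SAT1 on brighter ones, 1.73-fold for TAGLN2, 1.52-fold for CDK1, 1.58-fold for JAG1 and 1.10-fold for TMPO.

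The genes with lower signal and the smallest p-values, again none past the threshold, were led by ALDH7A1 and KISS1. ALDH7A1, an aldehyde dehydrogenase of lysine breakdown, had a signal of 3898 ± 1390 with siLuc and 953.3 ± 286 with siPTHrP (SD, n = 3), a log2 fold change of -1.99 (SE 0.26, limma adjusted p = 0.133). KISS1 had 8659 ± 1840 and 3469 ± 218 (-1.29, SE 0.19, adjusted p = 0.140). CCDC85B, a coiled-coil protein, had 6795 ± 1940 and 1884 ± 1960 on one probe set (-2.30, SE 0.37, adjusted p = 0.215), while its other probe set, with brighter signal, gave -0.069. The acid-sensing ion channel ASIC1 stood at 0.222-fold, ACLY, which makes cytosolic acetyl-CoA, at 0.495-fold, ADCY3, an adenylyl cyclase, at 0.441-fold, and ITGA6, the integrin alpha 6 chain, at 0.473-fold. PTCRA stood at 0.446-fold, the ribosomal stalk protein RPLP2 at 0.313-fold, the actin regulator CTTN at 0.485-fold, ATF6, a sensor of unfolded proteins, at 0.294-fold and the translation factor EIF5A at 0.462-fold. Other probe sets of CTTN, ATF6 and EIF5A did not all share this sign: 1 of 2 did for CTTN, 0 of 1 for ATF6 and 1 of 2 for EIF5A. Another probe set of ADCY3 gave 0.687-fold, and those of PTCRA gave 0.735-fold and 0.283-fold. Adjusted p-values of these last 9 genes lay between 0.287 and 0.321. All 24 genes named here passed the threshold with array weights, 13 passed without experiment 1, and 0 passed without the siLuc array of experiment 1 and with no replicate block, a setting chosen after seeing the data. JAG1, KISS1 and ALDH7A1 were among those 13, at limma adjusted p = 0.00913, 0.00854 and 0.00854. The genes had been chosen for small p-values on arrays that include these, so passing there is no independent support.

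**Figure D2:**
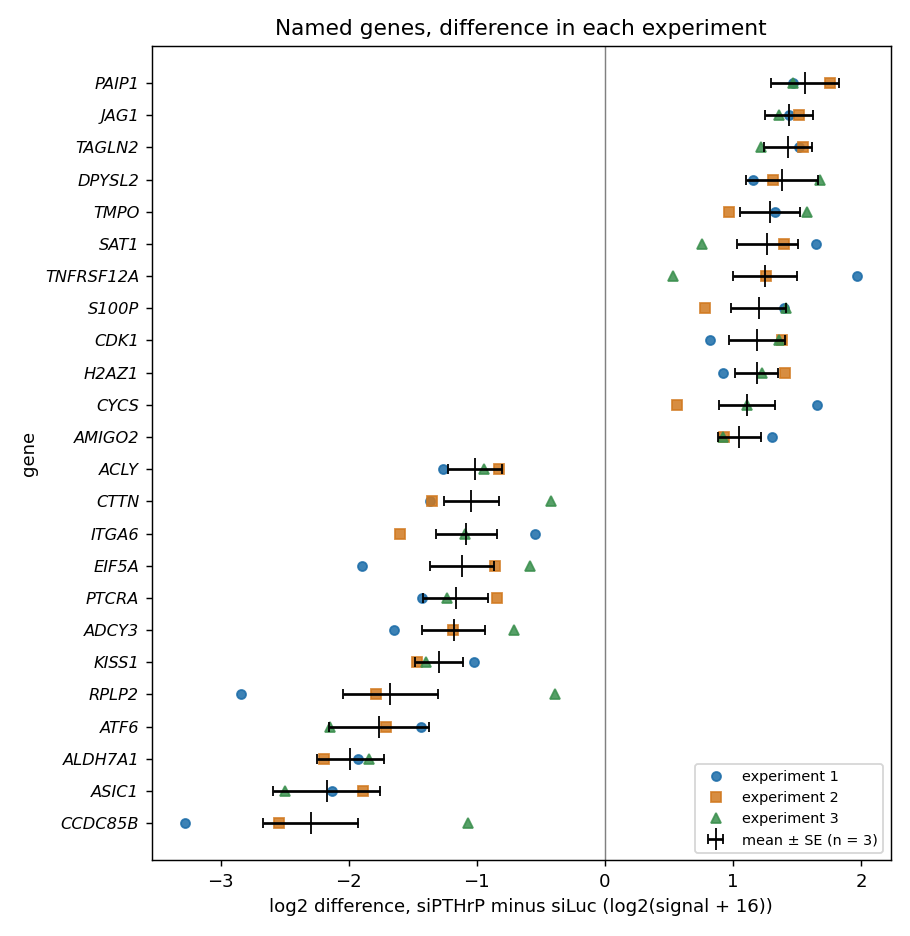
Log2 difference between siPTHrP and siLuc, on the log2(signal + 16) scale, for the 24 genes of the naming rule. Coloured symbols are the 3 experiments and the black bar is the fitted mean with its SE. For ALDH7A1 the fitted value is -1.99 and for JAG1 1.44. Each gene lies on 1 side of 0 in all 3 experiments, as the naming rule required.

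Genes of G2/M and mitosis, a list fixed before the data were examined, were higher with siPTHrP in 33 of 38 measured members, with a median log2 fold change of 0.57. The list passed limma's camera test with a preset correlation between genes of 0.01 (adjusted p = 5.31e-09 over 25 lists). With an estimated correlation it did not (adjusted p = 0.440 with an estimated correlation), and neither did it with fry (adjusted p = 0.0742). Its median was 0.64, 0.52 and 0.46 in experiments 1, 2 and 3. No member passed over all probe sets; 15 passed when adjusted over the list alone, all of them higher with siPTHrP except CENPA, the centromeric histone, at 0.591-fold. The others included CDCA8, a subunit of the chromosomal passenger complex, at 3.05-fold (log2 fold change 1.61, SE 0.33, list-adjusted p = 0.0304), the kinase NEK2 at 2.21-fold (1.15, SE 0.31, 0.0328), the topoisomerase TOP2A at 1.77-fold (0.82, SE 0.22, 0.0328) and CKS2, a CDK-binding protein, at 1.54-fold (0.62, SE 0.16, 0.0328). CDK1 passed there on its brightest probe set at 1.76-fold (0.82, SE 0.19, 0.0328), and cyclins CCNB1 and CCNB2 at 1.67-fold and 1.92-fold. Genes of DNA replication and G1/S were above 0 in 22 of 34 members, with a median of 0.18, and did not pass (camera adjusted p = 0.129, and 0.776 with an estimated correlation). Without experiment 1 that list passed with a median of 0.18 (adjusted p = 0.00802, and adjusted p = 0.789 with an estimated correlation). It did not pass without experiment 2 (median 0.23, adjusted p = 0.286) or without experiment 3 (median 0.038, adjusted p = 0.317). Over its 19 alternatives the list passed in 6, among them no filter (camera adjusted p = 0.0123) and array weights (camera adjusted p = 0.0219). Among its members TYMS, thymidylate synthase, stood at 1.51-fold, RRM2, a subunit of ribonucleotide reductase, at 1.48-fold, TK1, thymidine kinase, at 3.10-fold and RFC4, a clamp loader subunit, at 1.56-fold, with unadjusted p-values from 0.00765 to 0.0199 in limma.

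The unfolded protein and amino acid stress response list rose with siPTHrP in the camera test, with a median log2 fold change of 0.26 and 27 of 32 members above 0 (adjusted p = 0.00296). The call was lost with an estimated correlation (adjusted p = 0.776 with an estimated correlation), with quantile normalization (median 0.14, adjusted p = 0.483) and without experiment 2 (median 0.21, adjusted p = 0.0702). Random lists matched on intensity had a median of 0.17, and the stress response list lay at their 91.06th percentile. Its median was 0.41, 0.31 and 0.071 in experiments 1, 2 and 3, at the 80.09th, 99.96th and 42.9th percentiles of such lists. Adjusted over the list alone, 6 members passed at 0.0498. CTH, an enzyme of cysteine synthesis, stood at 1.85-fold, the stress-induced pseudokinase TRIB3 at 1.63-fold, the transcription factor CEBPB at 1.57-fold, HERPUD1, which acts in the degradation of misfolded proteins, at 1.52-fold and NUPR1 at 2.83-fold. The chaperone CALR was the exception at 0.625-fold. Genes of ribosomal proteins fell in the camera test, with a median of -0.17 and 40 of 48 members below 0 (adjusted p = 0.000186), but with quantile normalization their median was 0.0089 (adjusted p = 0.713). The call was also lost with an estimated correlation (adjusted p = 0.776 with an estimated correlation), without experiment 1 (median -0.13, adjusted p = 0.258) and without probe sets of the _x_at and _s_at kinds (median -0.13, adjusted p = 0.376). No ribosomal member passed over the list alone. RPLP2 stood at 0.313-fold, RPL37A at 0.658-fold, RPS18 at 0.598-fold and RPS10 at 0.672-fold. The log2 fold change of RPS10 turned to 0.14 with quantile normalization. On these same arrays the median of the ribosomal list was -0.31, -0.20 and -0.037 in experiments 1, 2 and 3, and the hybridisation controls differed between the 2 arrays of experiments 1 and 2 but not of experiment 3.

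**Figure D3:**
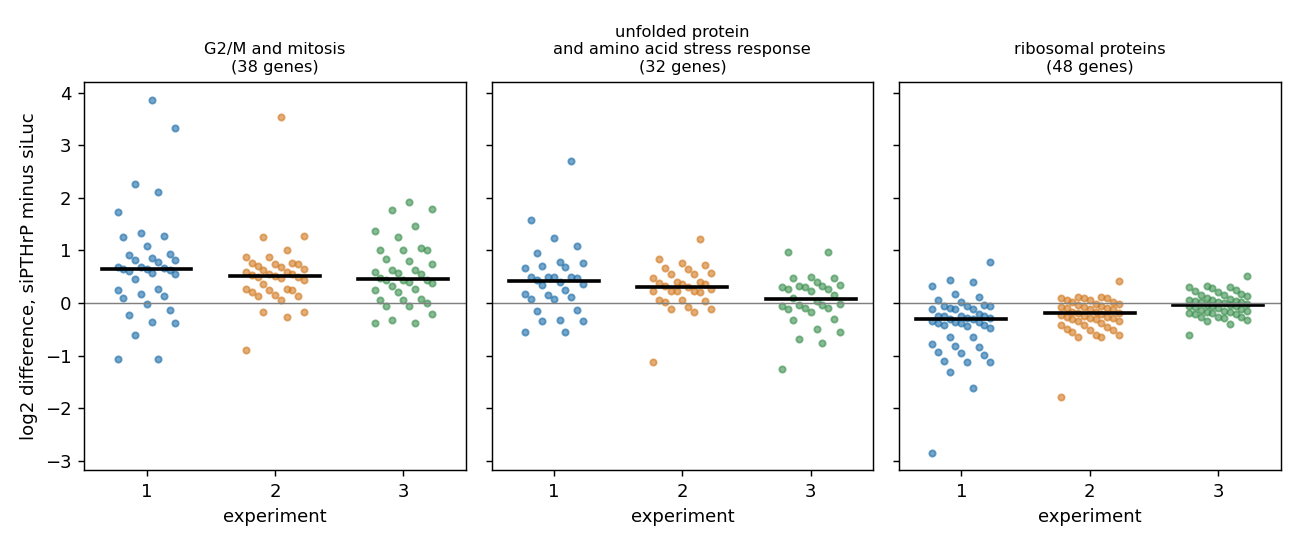
Log2 difference between siPTHrP and siLuc of each measured member of the 3 gene lists past the camera threshold, by experiment. Each point is 1 gene and the black line is the list's median, which is 0.64, 0.52 and 0.46 for G2/M and mitosis, 0.41, 0.31 and 0.071 for the unfolded protein and stress response and -0.31, -0.20 and -0.037 for ribosomal proteins.

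Components of PTHrP receptor and cAMP signalling were below 0 in 13 of 19 members, with a median log2 fold change of -0.20, and the list did not pass (camera adjusted p = 0.129). The adenylyl cyclase ADCY3 passed when adjusted over the list alone on its probe set at 0.441-fold (log2 fold change -1.18, SE 0.25, list-adjusted p = 0.0178). The arrestin ARRB1 stood at 0.533-fold, the transcription factor CREB1 at 0.559-fold and PRKACA, a catalytic subunit of protein kinase A, at 0.413-fold, each with a list-adjusted p of 0.155. For PRKACA the log2 difference was -1.284, -0.067 and -2.473 in experiments 1, 2 and 3. The cAMP and immediate early response genes had a median of 0.12 over 16 members, 11 above 0, and did not pass (adjusted p = 0.272). IER2 stood at 1.66-fold, the transcription factor KLF4 at 1.84-fold, and the phosphatases DUSP6 and DUSP1 at 1.53-fold and 2.13-fold, none past the threshold over the list alone. The log2 difference of DUSP1 was 3.07, 0.19 and 0.0040 in experiments 1, 2 and 3. The list passed in 1 of 19 alternatives, without experiment 3 (median 0.28, adjusted p = 0.0491), where the call was lost with another correlation (adjusted p = 0.892 with an estimated correlation).

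Bone metastasis and osteolysis genes showed no common direction, with 10 of 22 members above 0 and a median of -0.015 (camera adjusted p = 0.657). Their test of change in either direction, the mixed form of fry, gave an adjusted p of 0.0160. Adjusted over the list alone, JAG1 passed at 2.41-fold on its brightest probe set (log2 fold change 1.27, SE 0.21, list-adjusted p = 0.00419). The collagenase MMP1 passed at 0.396-fold (-1.34, SE 0.32, list-adjusted p = 0.0249), with -0.22, -2.12 and -1.67 in experiments 1, 2 and 3. Without experiment 1 MMP1 had the smallest p of all probe sets, with a log2 fold change of -1.89 and an adjusted p of 0.00152, and over its 16 alternatives the adjusted p ranged from 0.00128 to 0.532. The proteoglycan SRGN stood at 0.673-fold and the protease ADAMTS1 at 0.549-fold. Extracellular proteases and inhibitors had 15 of 28 members above 0, a median of 0.053, a mean of -0.13 and a downward direction in camera (adjusted p = 0.657). PLAU, the urokinase, stood at 1.55-fold and the membrane protease MMP14 at 0.695-fold. Integrins, laminins and adhesion genes had 17 of 25 members above 0 and a median of 0.23 (adjusted p = 0.450). Without experiment 1 that median was -0.085. Adjusted over the list alone 4 members passed: ITGA6 at 0.473-fold, COL4A2, a basement membrane collagen chain, at 1.76-fold, the laminin chain LAMA5 at 1.85-fold and the integrin chain ITGAV at 2.02-fold.

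Genes of cell death did not pass as groups. Pro-apoptotic genes had 11 of 20 members above 0 and a median of 0.17 (camera adjusted p = 0.650), and CYCS passed over the list alone (list-adjusted p = 0.0114), ahead of PMAIP1 at 1.51-fold, DIABLO at 1.56-fold and TRADD at 1.66-fold. Anti-apoptotic genes had a median of 0.15 over 15 members (adjusted p = 0.650), with API5 at 0.710-fold, BCL2L1 at 1.32-fold, BCL2 at 0.606-fold and TNFAIP3 at 2.07-fold. The p53 target genes had a median of 0.22 over 14 members (adjusted p = 0.650), with the cytokine GDF15 at 1.77-fold, SESN1 at 0.549-fold, GADD45A at 1.23-fold and XPC at 1.47-fold. TNFAIP3 and XPC turned to log2 fold changes of -0.23 and -0.069 without experiment 1.

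The NF-kB, interferon and heat shock lists gave no shift past the threshold. NF-kB target cytokines and regulators had a median of -0.014 over 19 members (camera adjusted p = 0.717), with the cytokines LIF at 1.89-fold and IL1A at 0.404-fold and the subunit NFKB1 at 0.755-fold. Interferon-stimulated genes had a median of 0.17 over 35 members (adjusted p = 0.785), with PML at 0.511-fold, IFIT5 at 2.12-fold, IFIT1 at 2.27-fold and OAS3 at 0.465-fold, and the mixed form of fry gave an adjusted p of 0.0437. Heat shock response genes had a median of -0.0084 over 12 members (adjusted p = 0.657). There the chaperone HSP90AA1 passed over the list alone at 0.618-fold (log2 fold change -0.69, SE 0.17, list-adjusted p = 0.0312), while DNAJB1 stood at 1.44-fold, CRYAB at 0.296-fold (log2 differences of -3.49, -1.03 and -0.76 in experiments 1, 2 and 3) and HSPE1 at 0.730-fold.

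Metabolic and growth factor lists did not pass either. Cholesterol biosynthesis and uptake genes had a median of 0.20 over 19 members (camera adjusted p = 0.650), with ACLY past the threshold over the list alone at 0.563-fold on its brightest probe set (list-adjusted p = 0.0165), TM7SF2 at 2.02-fold, SQLE at 1.52-fold and HMGCS1 at 1.52-fold. Hypoxia and glycolysis genes had a median of 0.067 over 31 members (adjusted p = 0.650), with BHLHE40 at 1.76-fold, the glucose transporter SLC2A3 at 3.15-fold (log2 differences of 3.70, 0.76 and 0.51 in experiments 1, 2 and 3) and PGAM1 at 1.42-fold. The mitochondrial respiratory chain had a median of 0.18 over 44 members, 33 of them above 0 (adjusted p = 0.134), with SDHA at 0.576-fold, NDUFS3 at 1.57-fold, UQCRC1 at 1.42-fold and NDUFB3 at 0.678-fold. That list passed in 1 of 19 alternatives, with no filter on low signal (median 0.18, camera adjusted p = 0.00738). TGF-beta response genes had a median of 0.10 over 22 members (adjusted p = 0.456), with TGFB1 at 1.55-fold, KLF10 at 1.91-fold and SMAD7 at 3.20-fold (3.46, 1.44 and 0.14). ETS transcription factors had a median of -0.017, a mean of 0.020 and a downward direction in camera over 16 members (adjusted p = 0.965), with ELF3 at 0.417-fold, ELF1 at 2.93-fold, ELK4 at 3.12-fold and ELK3 at 1.76-fold. Receptor tyrosine kinases and ligands had a median of -0.052 over 27 members (adjusted p = 0.657), with the ligand PDGFC past the threshold over the list alone at 1.60-fold (list-adjusted p = 0.04996), the receptor EPHB4 at 0.365-fold, NRG1 at 2.98-fold and HGF at 0.454-fold.

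The tested lists of cell type markers did not shift past the threshold. Luminal epithelial markers had a median of -0.18 over 16 members (camera adjusted p = 0.641), with XBP1 at 1.55-fold, KRT19 at 1.78-fold and ESR1 at 0.470-fold. Fibroblast markers had a median of -0.37 over 6 members (adjusted p = 0.272), with DCN at 0.386-fold, THY1 at 0.699-fold, FBN1 at 0.696-fold and COL1A1 at 0.861-fold. Mesenchymal markers, the class of this line, had a median of -0.037, a mean of 0.00071 and an upward direction in camera over 14 members (adjusted p = 0.717), with ZEB1 at 1.68-fold, FN1 at 1.38-fold, CDH11 at 1.30-fold and LOX at 1.35-fold. Only 4 leucocyte markers were measured above the filter, too few for the test, with MS4A1 at 0.378-fold, CD3E at 0.751-fold, ITGAM at 0.879-fold and CD79A at 1.03-fold. With no filter on low signal 16 leucocyte markers were measured, and that list passed with a median of -0.82 (camera adjusted p = 0.025003, and adjusted p = 0.701 with an estimated correlation). With the filter and 5 markers it did not pass without experiment 1 (median -0.16, adjusted p = 0.633) or with the siLuc array of experiment 1 left out and no replicate block (median -0.060, adjusted p = 0.572). The reference (housekeeping) genes had a median of -0.25 over 11 members (adjusted p = 0.430), with TFRC at 0.747-fold, GAPDH at 0.697-fold and ACTB at 0.728-fold.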

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

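The array's poly-A control probe sets, 27 probe sets for Bacillus transcripts that belong to no comparison above, were higher on every siPTHrP array than on every siLuc array. Their geometric mean signal lay between 3537 and 4040 with siLuc and between 4208 and 5239 with siPTHrP, a ratio of 1.21-fold. An exact two-sided permutation test of 3 against 3 arrays gave p = 0.1, the smallest it can give. That value follows from the complete separation and adds no evidence to it. For the hybridisation and ribosomal RNA controls, where the groups overlapped, the exact two-sided permutation test gave p = 0.2 and p = 0.3. The test did not use the pairing by experiment.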

How the results depend on the processing

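The 24 named genes kept their direction in all 16 alternatives in which they were measured and passed the threshold in at least 1 of them. They were chosen on these same arrays for a small p and the same direction in each experiment. The kept direction therefore followed largely from the naming rule and is no independent support. Probe sets past the threshold, 0 in the main analysis, numbered 0 under 10 alternatives: no replicate block, offsets 1 and 64, quantile normalization, median centring, no filter, the 60th percentile filter, no trend, a robust trend, and, added after seeing the data, no replicate block without the siLuc array of experiment 1. They numbered 177 with array weights (100 higher, 77 lower), 5 without _x_at and _s_at probe sets (3 higher, 2 lower) and, also added after seeing the data, 35 with no replicate block and array weights (24 higher, 11 lower). Leaving out 1 experiment gave 33 to 215 (21 to 146 higher, 12 to 69 lower), with 33 without experiment 1, 47 without experiment 2 and 215 without experiment 3; 10 were shared by the first pair and 41 by the last pair. At least 1.5-fold in each experiment, with no test, held for 597 (193 higher, 404 lower), and turning the sign of 1 experiment gave 139 to 209. The cause of these differences was not tested. Gene lists past the threshold, 3 in the main analysis, numbered 1 with quantile normalization, 6 with no filter, and 0 with an estimated correlation and with fry; leaving out 1 experiment gave 2 to 4. Without a replicate block the counts of 0 probe sets and 3 lists stayed, but with array weights the count was 177 with the block and 35 with no block. The G2/M and mitosis list passed in 17 of 19 alternatives, the stress response list in 15 and the ribosomal list in 14.

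Of 473 list medians under alternatives 57 changed sign, and 1 of these, that of ribosomal proteins with quantile normalization (0.0089), belonged to a list past the threshold. The same setting gave NF-kB 0.020, ETS 0.15, mesenchymal 0.058, ITGAM 0.13 and RPS10 0.14. Median centring gave bone metastasis 0.066, NF-kB 0.067, ETS 0.065, receptor tyrosine kinases 0.029, mesenchymal 0.044 and heat shock 0.073. No filter gave cAMP response -0.019, pro-apoptotic -0.21 and mesenchymal 0.11, and the 60th percentile filter gave bone metastasis 0.043, NF-kB 0.017, ETS 0.17, receptor tyrosine kinases 0.027 and mesenchymal 0.11. Array weights gave proteases -0.058, integrins -0.0066, mesenchymal 0.014, HSPE1 0.0047 and CD79A -0.25. Without _x_at and _s_at probe sets the values were cAMP response -0.044, pro-apoptotic -0.29, anti-apoptotic -0.12, ETS 0.38, receptor tyrosine kinases 0.050, mesenchymal 0.19 and heat shock 0.18. No replicate block without the siLuc array of experiment 1 gave pro-apoptotic -0.017, proteases -0.0070, integrins -0.043, TGF-beta -0.039, luminal 0.018, mesenchymal 0.23, TNFAIP3 -0.17, CD3E 0.14, CD79A -0.061 and XPC -0.092. No replicate block with array weights gave mesenchymal 0.12, HSPE1 0.089, ITGAM 0.041, CD79A -0.29 and XPC -0.086. The mean of all probe sets of a gene gave anti-apoptotic -0.026, proteases -0.0023, NF-kB 0.0096, ETS 0.12, mesenchymal 0.035 and heat shock 0.079. Leaving out 1 experiment gave ranges of -0.19 to 0.26 for pro-apoptotic, -0.16 to 0.16 for anti-apoptotic, -0.34 to 0.12 for bone metastasis, -0.13 to 0.17 for proteases, -0.085 to 0.41 for integrins, -0.23 to 0.13 for NF-kB, -0.031 to 0.18 for cholesterol, -0.073 to 0.43 for TGF-beta, -0.11 to 0.11 for ETS, -0.11 to 0.058 for receptor tyrosine kinases, -0.27 to 0.082 for luminal, -0.079 to 0.19 for mesenchymal and -0.048 to 0.070 for heat shock genes. It also gave -0.23 to 1.78 for TNFAIP3, -1.02 to 0.26 for CD3E, -0.11 to 0.46 for CD79A and -0.069 to 1.04 for XPC. The cause was not tested.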

Other observations

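The tests of hybridisation strength and of a separate MAS5 run for the siLuc array of experiment 1, the tests without experiment 1, the requirement that random lists match the ribosomal list in brightness, the splits for probe sets and the metallothionein values were chosen after the results were seen.

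Metallothioneins, small cysteine-rich proteins that bind zinc and copper, had lower signal with siPTHrP on all 10 kept probe sets of 7 genes, with a median log2 fold change of -0.74 and none past the threshold in limma. In 9 of the 10 the difference was below 0 in each of the 3 experiments, with medians of -0.77, -0.76 and -0.56 in experiments 1, 2 and 3. MT2A had a signal of 257000 ± 30900 with siLuc and 136300 ± 42300 with siPTHrP (SD, n = 3; log2 fold change -0.95, SE 0.21, adjusted p = 0.321), MT1H 120000 ± 13700 and 63860 ± 8150 (-0.91, SE 0.18, adjusted p = 0.287), and MT1X on its brighter probe set 144500 ± 16300 and 82600 ± 7260 (-0.80, SE 0.18, adjusted p = 0.321). All 10 remained below 0 with quantile normalization (median -0.48), with median centring (median -0.66) and without experiment 1 (median -0.73). The family's transcripts are near-identical, so that probe sets can read each other's transcripts and the members are not independent.

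The siLuc array of experiment 1 differed from the other 5. Lists of markers argued against enough luminal, leucocyte or fibroblast cells in the culture to shift these lists as a whole. Fewer such cells, or cells of other types, stay open. The highest of the luminal, leucocyte and fibroblast lists lay at the 86.67th percentile of random lists matched on intensity, under the bound set in advance. Their brightest members were mixed, with KRT18 at 10610 on this array and 11680 on the other siLuc arrays, but CD8A at 2004 and 129.5 and THY1 at 2505 and 1060, so that single markers stay unexplained. Weak hybridisation of the sample, scaled up afterwards, is a candidate explanation, since the controls added in a fixed amount were 8.87-fold higher than on the other siLuc arrays. Probe sets in the dimmest of 5 intensity classes were raised on this array by a median of 1.34 (log2), and those in the brightest were lowered by 0.278 (median -0.278). The classes were formed on the other 5 arrays, and any array that correlates weakly with them would show this, so it does not tell causes apart. A separate MAS5 run of this array, with decimals in 90.1% of values, could not be told apart from weak hybridisation, because the scanner files were not used here.

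The G2/M and mitosis list was higher with siPTHrP. A difference in hybridisation strength as the whole cause is argued against by experiment 3, where the controls of the 2 arrays differed by 0.971-fold and the list's median of 0.46 lay at the 100th percentile of random lists matched on intensity (their central 95% was -0.15 to 0.19). The siLuc array of experiment 1 alone is argued against as well by experiments 2 and 3, which do not hold it. The list's medians there were 0.52 and 0.46, both at the 100th percentile of such random lists. Without experiment 1 the list passed camera at the preset correlation (median 0.49, adjusted p = 2.476e-10, with a range over its 19 alternatives of 1.78e-13 to 0.440). For that fit no value with an estimated correlation is given for this list. The hypothesis that cells given siPTHrP held more transcripts of dividing cells, because of the siRNA, may be followed up, but an effect of the siRNA on other transcripts and differences in cell density stay open and were not tested. The call was lost with an estimated correlation, but camera then uses only the 2 residual degrees of freedom. That loss cannot tell correlation between these genes from the small number of arrays, so correlation was not decided.

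The ribosomal protein list was lower with siPTHrP. Its median lay at the 0.02th percentile of random lists matched on intensity, which met the bound set in advance for arguing against brightness of the probe sets as the cause. After this was seen, the draws were found to be dimmer than the list by a median of 1.35 (log2), and the test was then taken as undecided. After quantile normalization, which removes differences that depend on brightness, the list had a median of 0.0089, at the 56.71th percentile. Those draws followed the same matching rule, so this percentile is undecided as well. The normalization can also remove a real fall of bright probe sets, so these values do not decide on brightness. On the siLuc array of experiment 1 as the only source the values were divided: without experiment 1 the median was -0.1269 and not past the threshold (adjusted p = 0.258), but without this array alone and with no replicate block it was -0.22 and passed (adjusted p = 0.0153), so this stays open.

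The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 0 probe sets past the threshold, so that 10 of the 10 splits gave as many by definition and this count tests nothing; the highest other gave 737. The 4 splits that part all 3 experiments gave 0 each, and at an unadjusted p under 0.05 the real split gave 1618 probe sets and the other 3 gave 192 to 393. Those 3 turn the sign of 1 experiment, so any difference shared by the experiments enters their residual variance. Their counts, below the 666 expected by chance, are therefore no fair measure of chance. Each of the other 6 splits parts only 1 experiment, and the highest count came from those that part experiment 1, which points to a structure of the samples. Such a split compares the 2 arrays of that experiment, so that array differences and any effect of the siRNA are mixed in its count, and the cause was not tested. For gene lists the real split gave 3 past the threshold, 4 of the 10 splits gave as many, and the highest other gave 4, which was also the highest among those that part all 3 experiments. Splits that part only 1 experiment come in pairs that are the same comparison. The sign is turned within the pairs parting experiments 2 and 3. It is the same within the pair parting experiment 1 (G2/M median 0.64 in both). The pair parting experiment 2 (G2/M median 0.52 and -0.52) is counted separately among the 4 of 10 splits. It is that experiment's own contrast of siPTHrP and siLuc, so this share is no measure of chance.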
